A study of Homo sapiens with 8 samples.

How the data were processed

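Human H1 embryonic stem cells, an established pluripotent line, were grown in FTDA medium and differentiated towards cardiomyocytes, per the labels' protocols. RNA was extracted with TriZol, enriched for polyadenylated molecules and made into libraries with a standard Illumina preparation, per the labels' protocols. There were 8 libraries, 2 from each of days 2, 4, 6 and 8, which were the 4 groups compared. The labels number the replicates of each day and do not say whether they came from separate cultures. All p-values therefore measure only the spread between these samples.

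The deposited file is a table of raw read counts, with 1 column per library. Per the submitters' processing notes, the genome build was hg38 and the tools were STAR 2.5.0 and Cufflinks 2.2.1, with no role given for either. The counting program, its strand setting, its treatment of reads with several matches and the annotation release are not given in the sources used here. The table held 61564 rows, of which 1010 carried names that begin with yylnc, called yylncRNA rows in this text. After removal of 80 exact repeats, 61484 rows were kept, of which 939 were yylncRNA rows; 436 of these measured exactly 1000 bases from start to end. No count in any library was recorded for 4282 rows. Gene names were looked up in GENCODE 44: 37044 rows matched, 1644 of them through an older symbol, and 23501 did not. The row named T in the file is TBXT.

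The deposited counts were tested for the way in which reads were assigned. Of 6805 pairs of rows with 1 nested inside the other on the same strand (inner row with at least 50 counts), the inner row exceeded the outer in 21, and on opposite strands in 6 of 8092. Counts were therefore read as counts over whole intervals, introns included, on both strands, with a read given in full to every row it overlaps. Of the kept rows, 36332 overlap another row and 25152 overlap none. A gene is said to share reads where an overlapping row held at least 0.5 times its total count. Of the genes named in this text these are ACTC1, ALDOC, CSRP3, DDIT4, DLL1, EVX1, GPI, HAND2, HAND2-AS1, KDR, KRT18, LEFTY1, MBD3, NPPA, POU5F1, RNF43, SLC8A1, SOX2, TAGLN, TCF21, TCF7, TNNI3, ZIC1 and, of HOXB1 to HOXB8, all but HOXB1. Column sums exceed the reads counted for the same reason, so the totals given as depth are totals of the table.

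Changes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation factors, filterByExpr with a minimum count of 10, a quasi-likelihood fit over all 8 libraries with 1 coefficient per day, and Benjamini-Hochberg (BH) adjustment at 0.05 with no fold minimum. The filter removed 22739 rows and left 38745. Every adjusted p of a single gene is from this edgeR quasi-likelihood test unless another tool is named. The 4 comparisons were day 4 against day 2, day 6 against day 4, day 8 against day 6, and day 8 against day 2. A quasi-likelihood F test over all days put each changed row under the day of its highest mean. The common biological coefficient of variation was 0.272, with 2.95 prior degrees of freedom. CPM are counts scaled to the TMM-adjusted size of each library, and values are mean CPM ± SD over n = 2 libraries unless stated otherwise. Log2 fold changes are given ± SE. Where a day had no count in either library, a fold is a bound against a floor of 3 counts over the group; these floors and all intervals cover counting or resampling error only.

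The lists of genes, the tests and the alternative settings were fixed before the data were examined. There were 22 lists: pluripotency, primitive streak, paraxial mesoderm, cardiac mesoderm, cardiac transcription factors, sarcomere, calcium handling and ion channels, other cardiomyocyte genes, endoderm, endothelial and blood, neuroectoderm, epicardial and stromal, epithelial, cell cycle, DNA methylation, Wnt targets, BMP targets, oxidative phosphorylation, glycolysis, HOX genes, immediate early and stress, and long noncoding RNAs. Each was tested with camera (limma 3.58.1, two-sided, preset correlation between genes of 0.01) on log2 CPM with a prior count of 2, and the p-values were BH adjusted over the lists of a comparison. A list p is from camera unless another test is named. Beside it were run camera with an estimated correlation and fry. While camera compares the members with the other genes, fry tests the members alone against no change and gives a direction. That direction need not follow the fold changes. Long noncoding RNAs from day 2 to day 8 had a median of −0.51 and a mean of −1.24, with fry up. The fry p, also BH adjusted, is given where it and camera fall on different sides of 0.05. Of 88 list tests, 56 were past 0.05 with the preset correlation. With an estimated correlation 7 of these stayed past it. Primitive streak and cardiac transcription factors did so from day 2 to day 4. Primitive streak, cardiac transcription factors, sarcomere, calcium handling and ion channels, and other cardiomyocyte genes did so from day 2 to day 8. The camera p-values also rose where the estimated correlation lay below the preset 0.01. Primitive streak from day 2 to day 4, at −0.0574, went from 7.83e-10 to 0.0257. Wnt targets in the same comparison, at −0.00557, went from 0.00669 to 0.185. A call lost in this version therefore does not show that correlated members had made it.

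Genes were named by a rule set in advance. It took the 5 largest rises and 5 largest falls past the test with at least 10 CPM on 1 of the days and libraries that do not overlap; up to 4 members of each list with the largest changes; TBXT and DNMT3B in every comparison; and for each day the 3 genes with the highest ratio to the next highest day. The noncoding RNA yylncT was added because the series title names it. Members named because they make up a count of 5 or fewer, and EMC10, ALB and the rows inside EMC10, were chosen after their values were seen. Some single-gene results are left out of the text; where genes are given as among those that rose or fell, the names are not complete. Members outside the rule were not run singly under the alternative settings. Where leaving out any of several libraries ended the call of a gene, the library that gave the highest p is named.

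The procedure was tested on simulated counts for day 4 against day 2 over 37675 rows. They were drawn from the means over all days, the trended dispersions and the library sizes of these data. The scatter of single rows about that dispersion trend was left out, which also limits what the simulation can show for these data. At each size 50 genes were changed, drawn from rows with a mean of at least 50 counts. Far fewer rows were changed than were called in the data, so the recovery and false calls hold for this setting only. The edgeR test recovered 50% of 1.5-fold changes, 62% of 2-fold, 86% of 4-fold and 90% of 8-fold changes, with 4 false calls. DESeq2 1.42.0 made 59 false calls and limma-voom 10. The F test over all days recovered 73.5% of 200 changed genes with 6 false calls. A raised list of 40 genes was found by each list test; of 20 unchanged lists, none was called by camera or by directional fry and 1 by mixed fry.

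Alternatives tried for the counts of changed genes and the named genes were DESeq2 size factors, upper-quartile factors, library size alone, no low-count filter, a stricter filter, DESeq2, limma-voom, the 4 compared libraries alone, a log2 fold minimum of 1, an adjusted p of 0.01, and leaving out each library in turn. Alternatives chosen after the data were seen were rows that overlap no other row, protein-coding rows alone, the table without mitochondrial and 2 ribosomal DNA rows, and the lists without members that share reads. Sequence matches were searched with blastn 2.17.0 (word size 24). Y-linked transcripts and XIST were left out of the genes that could be named. Splits of the libraries into other groups were not counted, because groups of 2 cannot be tested in this way, and no rule for outlying samples applies to groups of 2.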

Results

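Polyadenylated RNA was sequenced from H1 human embryonic stem cells on their way to cardiomyocytes, with 2 libraries from each of 4 days. The labels call the day 2 cells late mesoderm and the day 4 cells cardiac mesoderm; those of day 6 are called cardiac progenitors and those of day 8 early cardiomyocytes. The series title names yylncT, a long noncoding RNA, and DNMT3B, a DNA methyltransferase. The table held between 110142743 and 127316412 counts per library. Transcripts of the mitochondrial genome took 5.2 ± 0.127% of the counts on day 2, 3.82 ± 0.0141% on day 4, 4.76 ± 0.212% on day 6 and 6.76 ± 0.0212% on day 8 (SD, n = 2).

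The libraries grouped by day. Along the first principal component of the 1000 most variable rows, which held 60.1% of their variance, the day 2 libraries lay at −121.5 and −119.5, both day 4 libraries at −7.5, the day 6 libraries at 61.9 and 61, and the day 8 libraries at 67.1 and 65.9. Across rows, which are not independent replicates, the log2 CPM of the libraries of a day correlated with r between 0.969 and 0.97.

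Over the whole course, pluripotency and primitive streak genes fell and cardiac transcription factors rose by day 4. Sarcomere genes rose from day 2 to day 4 and again from day 4 to day 6. Of 38745 rows tested, 25593 differed between days in the edgeR F test. Of these, 9819 were highest on day 2, 5386 on day 4, 3862 on day 6 and 6526 on day 8. TBXT, the T-box transcription factor of the primitive streak, was the gene most restricted to day 2, at 501 ± 9.43 CPM against 0.286 ± 0.0141 CPM on day 4. PGA3, a pepsinogen gene, reached 796 ± 3.34 CPM on day 4 and 19.4 CPM on its next highest day. NOS2, an inducible nitric oxide synthase, stood at 96.3 ± 3.45 CPM on day 4 against 0.942 ± 0.257 CPM on day 6. SHH, a secreted patterning signal, was highest on day 6 at 20.1 ± 6.33 CPM. STUM, a membrane protein gene, was highest on day 8 at 62.5 ± 3.19 CPM against 6.38 ± 1.64 CPM on day 6.

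**Figure D1:**
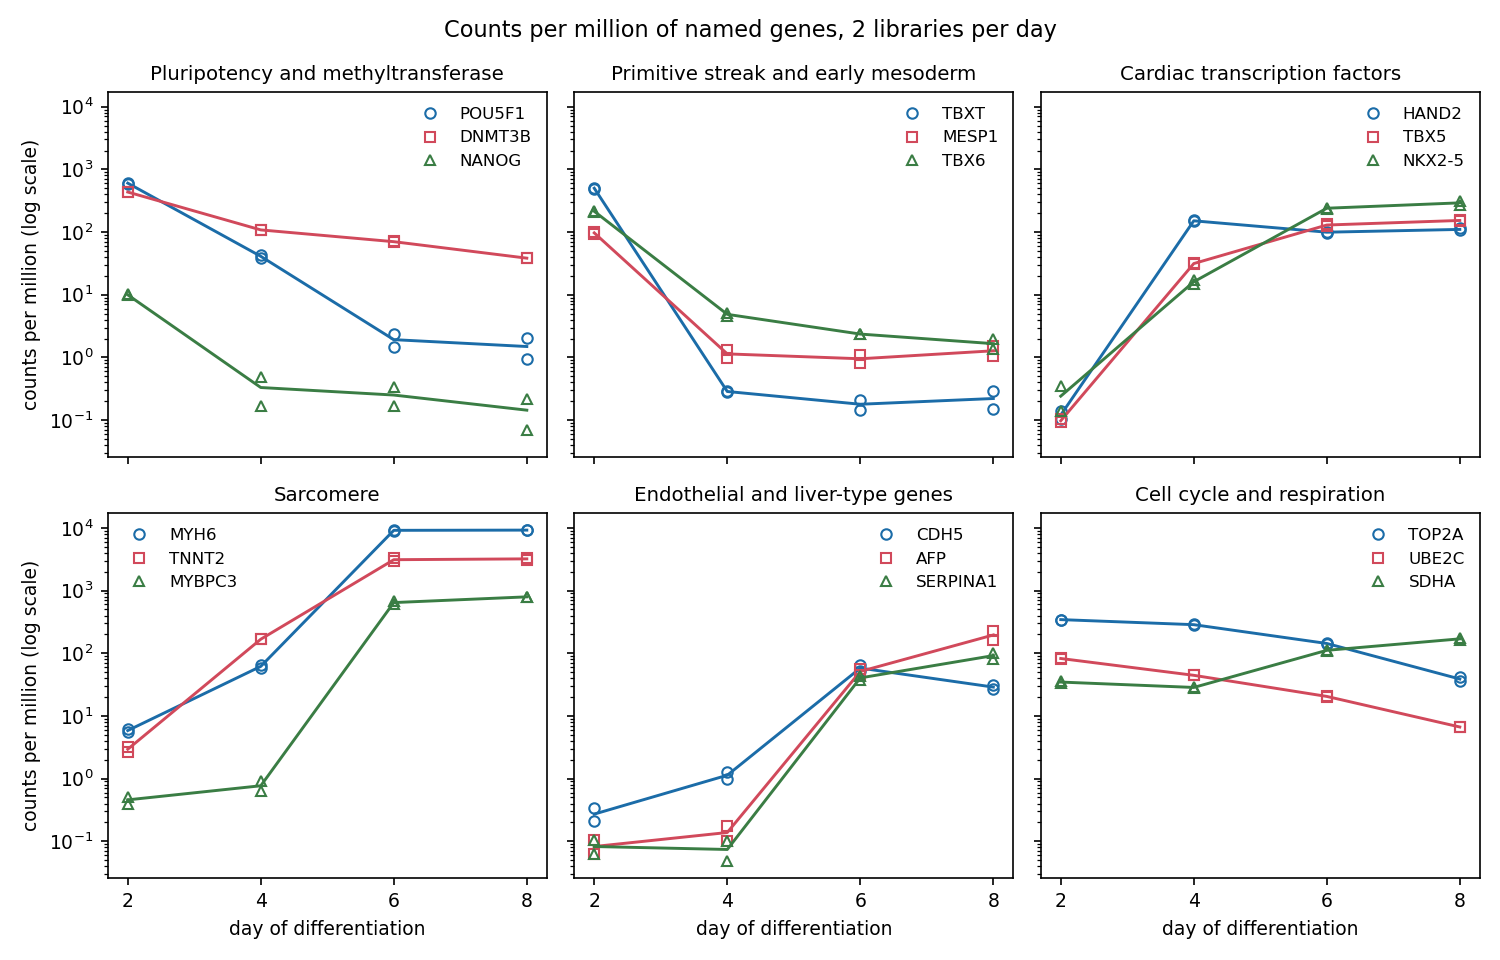
CPM (log axis) of 18 genes against day of differentiation; each symbol is 1 library and lines join the means of the 2 libraries of a day. TBXT fell from 501 CPM on day 2 to 0.286 on day 4, and MYH6 rose from 61.8 CPM on day 4 to 9150 on day 6.

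TBXT, yylncT and DNMT3B were each highest on day 2. TBXT lies on chromosome 6 (166157656 to 166168700, minus strand, hg38) and yylncT beside it on the plus strand (166169202 to 166170199, a row of 998 bases), 502 bases apart. GENCODE 44 places a long noncoding RNA gene, LNCDAT, from 166167920 to 166171376 on the plus strand, and the yylncT row lies wholly inside it. The yylncT row held 2174 and 2569 counts in the day 2 libraries, 0 and 4 on day 4, and 0 in all 4 libraries of days 6 and 8. Its fall from day 2 to day 4 had a log2 fold change of −10.11 ± 0.51 (edgeR adjusted p = 4.54e-05; DESeq2 adjusted p = 0.0516), and on day 8 it was at least 1410-fold lower than on day 2. In the day 2 libraries there were 26.4 and 25.7 TBXT counts for each yylncT count. The TBXT row covers 11045 bases, introns included, against 998, so this is not a ratio of transcript amounts. LNCDAT also overlaps the TBXT row from 166167920 to 166168700. With both strands counted, reads of LNCDAT there would fall under TBXT. After day 4, TBXT differed little between days: its log2 fold change was −0.68 ± 0.30 from day 4 to day 6 (adjusted p = 0.113; 0.0364 with DESeq2, and 0.0385 and 0.0386 without day 8 replicate 1 and replicate 2) and 0.33 ± 0.32 from day 6 to day 8 (adjusted p = 0.555; −0.23 with adjusted p = 0.779 without day 8 replicate 1). DNMT3B (chromosome 20, 32762385 to 32809356, plus strand) stood at 435 ± 0.994, 108 ± 1.28, 70.3 ± 2.5 and 38.4 ± 0.646 CPM on days 2, 4, 6 and 8. Its log2 fold changes between successive days were −2.01 ± 0.04 (adjusted p = 3.77e-08), −0.62 ± 0.04 (1.28e-05) and −0.87 ± 0.04 (3.21e-05).

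**Figure D2:**
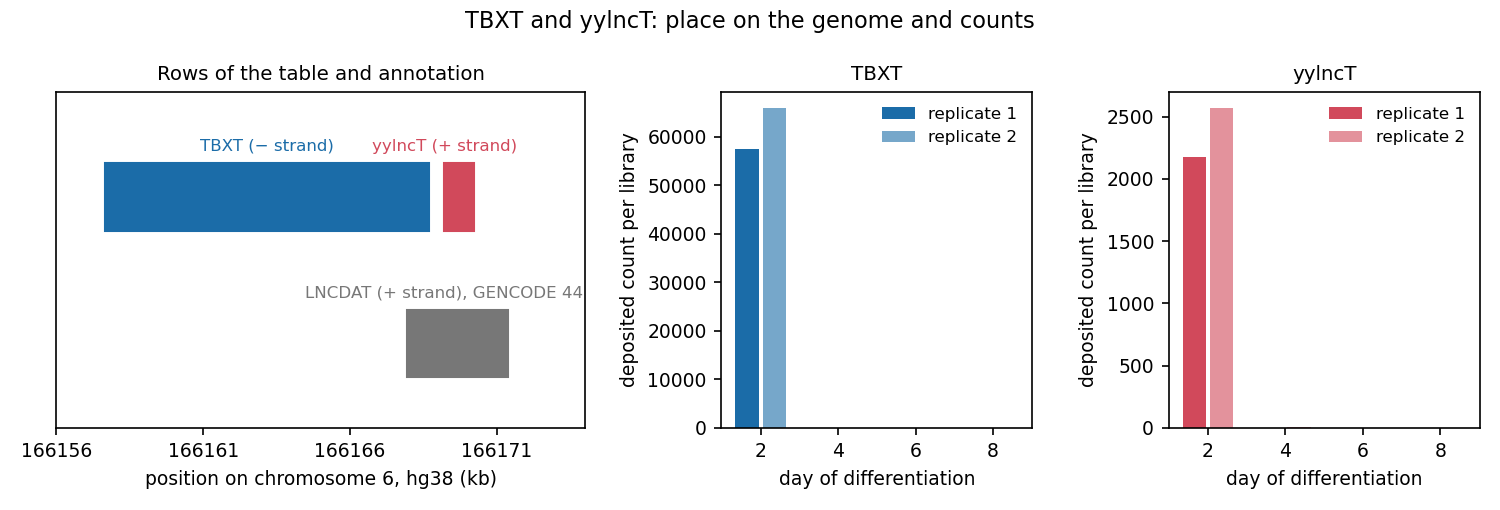
Left, positions of the TBXT and yylncT rows and of LNCDAT on chromosome 6 (kb, hg38); middle and right, deposited counts of TBXT and yylncT per library against day, 1 bar per replicate. The yylncT bars stand at 2174 and 2569 counts on day 2 and at 0 or 4 counts on later days.

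The comparison of day 4 with day 2 asks how cardiac mesoderm differed from late mesoderm. Primitive streak and paraxial mesoderm genes fell while cardiac transcription factors and sarcomere genes came up. Glycolysis and cell cycle genes fell at the same time, and epicardial and stromal genes rose. HAND2, a transcription factor of the early heart, rose from 0.121 ± 0.025 to 151 ± 4.62 CPM, with reads shared with the antisense HAND2-AS1 row. CBLN2, a secreted synaptic organiser, rose from 0.206 ± 0.122 to 307 ± 6.63 CPM, and NTRK2, a neurotrophin receptor, from 0.0713 ± 0.0573 to 86.3 ± 1.39 CPM. CER1, a secreted Nodal antagonist, fell from 362 ± 9.83 to 0.419 ± 0.0965 CPM (859-fold). In all, 9625 rows were higher on day 4 and 10124 lower, and among 17400 protein-coding rows 5591 were higher and 6619 lower. Over all rows the larger side depended on the setting, with 4662 higher and 4220 lower at a log2 fold change of at least 1.

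All 16 tested primitive streak genes fell from day 2 to day 4, over all rows tested and adjusted over the list alone, with a median log2 fold change of −7.10 (camera adjusted p = 7.83e-10; 0.0257 with an estimated correlation). FGF4, a growth factor of the streak, fell from 56.3 ± 4.24 to 0.0817 ± 0.00258 CPM (681-fold), and FGF17 from 130 ± 8.77 to 0.31 ± 0.0364 CPM. CDX2, a caudal homeobox factor, fell from 32.3 ± 4.02 to 0.0908 ± 0.0606 CPM. Of 12 paraxial mesoderm genes 9 fell, and PAX3 and UNCX rose; adjusted over the list alone MEOX1 rose as well (adjusted p = 0.00252; 0.185 with an estimated correlation). TBX6, which directs cells into presomitic mesoderm, fell from 214 ± 8.8 to 4.87 ± 0.424 CPM, and RIPPLY2 from 22.4 ± 2.02 to 0.42 ± 0.0272 CPM. Of 20 pluripotency genes 17 fell, by both adjustments (adjusted p = 8.17e-07; 0.185 with an estimated correlation). TDGF1, a Nodal co-receptor, fell from 217 ± 1.03 to 7.21 ± 0.0373 CPM and NANOG from 9.96 ± 0.32 to 0.331 ± 0.232 CPM. SOX2, which shares reads with SOX2-OT, did not pass (log2 fold change −0.99, adjusted p = 0.192), nor did DPPA2 (−0.43, 0.392) or UTF1 (−1.01, 0.547). The cardiac mesoderm list split, with 6 of 12 members higher and 5 lower (MESP1, MESP2, APLNR, SNAI1 and RSPO3). Its median was 0.64 and its mean −0.37, camera gave no call (up, adjusted p = 0.735) and fry gave a fall (adjusted p = 0.00498). MESP1, an early marker of heart precursors, fell from 97.1 ± 4.66 to 1.14 ± 0.221 CPM, and TMEM88, a Wnt inhibitor, rose from 2.8 ± 0.496 to 205 ± 3.95 CPM.

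Of 21 cardiac transcription factors 18 rose and HOPX fell (log2 fold change −1.52), by both adjustments, with a median of 5.12 (adjusted p = 1.4e-10; 0.0257 with an estimated correlation). TBX5, a regulator of chamber formation, rose from 0.0977 ± 0.00768 to 31.5 ± 0.139 CPM (319-fold) and SMYD1, a muscle methyltransferase, from 0.309 ± 0.0963 to 132 ± 1.99 CPM (420-fold). GATA6 (−0.08, adjusted p = 0.224) and IRX4 (0.62, 0.105) did not pass. Of 29 sarcomere genes 24 rose by both adjustments, while TNNI3 and CSRP3 fell (adjusted p = 7.83e-10; 0.169 with an estimated correlation). UNC45B, a myosin chaperone, rose from 0.25 ± 0.0378 to 53.9 ± 0.887 CPM, MYL4, an atrial myosin light chain, from 1.33 ± 0.0793 to 199 ± 10.1 CPM, and TNNT2, cardiac troponin T, from 2.94 ± 0.421 to 168 ± 0.898 CPM. Calcium handling genes went both ways, with 10 of 20 higher and 8 lower, or 11 and 9 adjusted over the list alone (adjusted p = 0.356, fry 1.99e-05). CACNA1D, a calcium channel, rose from 1.67 ± 0.179 to 45 ± 1.91 CPM, and TRDN, triadin of the sarcoplasmic reticulum, fell from 60.5 ± 1.44 to 3.77 ± 0.637 CPM. Of 14 other cardiomyocyte genes 9 rose and COX7A1 fell, by both adjustments (adjusted p = 0.0133; 0.185 with an estimated correlation), with MB, myoglobin, going from 0.152 ± 0.0522 to 1.88 ± 0.27 CPM.

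Epicardial and stromal genes and BMP targets rose from day 2 to day 4, and Wnt targets fell. In the epicardial and stromal list 11 of 15 genes rose and TAGLN and COL1A2 fell; adjusted over the list alone 12 rose and 3 fell (adjusted p = 0.00078; 0.279 with an estimated correlation). COL3A1 rose from 1.2 ± 0.00803 to 214 ± 20.3 CPM and COL1A1 from 90.2 ± 9.38 to 2610 ± 116 CPM. Of 10 BMP targets 8 rose and MSX1 fell, by both adjustments (adjusted p = 0.000216; 0.185 with an estimated correlation). SMAD6, an inhibitory SMAD, rose from 28.8 ± 1.61 to 256 ± 9.95 CPM and ID2 from 27.1 ± 1.44 to 147 ± 3.25 CPM. Of 12 Wnt targets 9 fell, and LEF1, RNF43 and LGR5 rose, by both adjustments (adjusted p = 0.00669; 0.185 with an estimated correlation). DKK1, a secreted Wnt inhibitor, fell from 63.6 ± 2.2 to 1.43 ± 0.232 CPM.

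All 27 cell cycle genes fell from day 2 to day 4 by both adjustments, with a median of −0.92 (adjusted p = 1.4e-10; 0.223 with an estimated correlation), and RRM2, a ribonucleotide reductase subunit, went from 116 ± 3.62 to 33.4 ± 0.923 CPM. Of 18 glycolysis genes 15 fell, and PFKM, PFKP and SLC2A3 rose, by both adjustments (adjusted p = 4.91e-05; 0.279 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 872 ± 30.4 to 261 ± 5.87 CPM and the hexokinase gene HK1 from 258 ± 0.546 to 66.5 ± 0.00789 CPM. Of 21 oxidative phosphorylation genes 16 fell, 17 adjusted over the list alone, and UQCRC2 and ATP5F1A rose (adjusted p = 0.00252; 0.579 with an estimated correlation). Of 14 DNA methylation genes 6 fell, by both adjustments, and DNMT3A, TET2, TET3 and MBD1 were among those that rose, with a median of 0.03 and a mean of −0.30 (down, adjusted p = 0.866, fry 0.00375). DNMT3A, the other de novo methyltransferase, rose from 73.1 ± 3.86 to 167 ± 4.66 CPM while DNMT3B fell. Endoderm genes rose in 10 of 17 cases by both adjustments, and SOX17, FOXA3 and CER1 fell (adjusted p = 0.031; 0.457 with an estimated correlation and 0.119 without members that share reads). Endothelial and blood genes went both ways, with 8 of 17 higher and 5 lower (TEK, TIE1, EGFL7, RUNX1 and ERG), by both adjustments (up, adjusted p = 0.459). Of 13 epithelial genes 8 fell, and CLDN3, KRT8, KRT18 and KRT19 rose, by both adjustments (down, adjusted p = 0.266, fry 0.00412). CDH1, E-cadherin, fell from 220 ± 10.1 to 56.6 ± 2.5 CPM and the keratin gene KRT19 rose from 245 ± 3.44 to 794 ± 14.6 CPM.

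The comparison of day 6 with day 4 asks what changed as cardiac mesoderm became cardiac progenitors. Contractile genes rose again, with a median log2 fold change of 3.58 against 3.19 in the step before, a difference that was not tested. Genes of calcium handling and of mitochondrial respiration rose with them. Endothelial and blood genes came up in the same libraries. Pluripotency, paraxial mesoderm, epithelial and cell cycle genes fell. MYBPC3, cardiac myosin binding protein C, rose from 0.769 ± 0.189 to 644 ± 41.6 CPM (834-fold), and MYH6, the α myosin heavy chain, from 61.8 ± 5.18 to 9150 ± 274 CPM (148-fold). In all, 8185 rows were higher on day 6 and 7803 lower, and among protein-coding rows 5431 were higher and 4990 lower, or 5575 and 5816 with protein-coding rows fitted alone. Over all rows, too, the larger side depended on the setting: 3458 were higher and 2424 lower at a log2 fold change of at least 1, against 2169 and 2459 over rows that overlap no other row and 6854 and 9552 with library size alone.

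Of 29 sarcomere genes 27 rose from day 4 to day 6 and none fell, by both adjustments. Their median was 3.58, or 3.48 with MYL2, absent on day 4, at its bound (adjusted p = 3.18e-20; 0.0526 with an estimated correlation). MYL2 (4.07, adjusted p = 0.159) and LMOD2 (0.47, 0.459) did not pass. MYOM1, which links thick filaments at the M band, rose from 2.08 ± 0.262 to 335 ± 19.3 CPM, and CSRP3, a Z-disc protein gene that shares reads with an overlapping row, from 0.0608 ± 0.0269 to 29.8 ± 2.11 CPM. SMPX, a small muscle protein outside the list, rose from 0.0977 ± 0.02 to 48.1 ± 3.69 CPM. Of 20 calcium handling genes 16 rose, 17 adjusted over the list alone, and KCNJ2 and GJA1 fell (adjusted p = 2.25e-07; 0.0526 with an estimated correlation). The sodium-calcium exchanger gene SLC8A1, which shares reads with its antisense row, rose from 15.4 ± 1.79 to 901 ± 16.9 CPM, and TRDN from 3.77 ± 0.637 to 176 ± 7.6 CPM. SLN, sarcolipin, had no count on day 4 and was at least 44.9-fold higher on day 6. Of 14 other cardiomyocyte genes 13 rose and BMP10 fell, by both adjustments (adjusted p = 9.02e-08; 0.0526 with an estimated correlation). CKM, muscle creatine kinase, rose from 0.873 ± 0.0533 to 124 ± 9.29 CPM, and PPARGC1A, a coactivator of mitochondrial genes, from 2.16 ± 0.351 to 75.1 ± 1.98 CPM.

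Among 21 cardiac transcription factors 14 rose, 15 adjusted over the list alone, and 5 fell (GATA6, ISL1, HAND2, MEIS1 and HEY1; adjusted p = 0.00488, 0.161 with an estimated correlation). NKX2-5, a core cardiac homeobox factor, rose from 16.1 ± 1.95 to 240 ± 5.97 CPM, and IRX4, a ventricular factor, from 1.33 ± 0.42 to 58.2 ± 9.46 CPM. All 21 oxidative phosphorylation genes rose by both adjustments, with a median of 0.85 (adjusted p = 4.54e-12; 0.226 with an estimated correlation). SDHA, the flavoprotein of complex II, rose from 28.5 ± 0.489 to 111 ± 3.36 CPM, and CYCS, cytochrome c, from 33.7 ± 0.425 to 110 ± 1.89 CPM. Of 18 glycolysis genes 14 rose and SLC2A3 fell, by both adjustments (camera adjusted p = 1.89e-05, and 0.257 with an estimated correlation). PDK1, a pyruvate dehydrogenase kinase, rose from 153 ± 5.72 to 646 ± 7.11 CPM.

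Of 17 endothelial and blood genes 15 rose from day 4 to day 6, and VWF and ETV2 fell, by both adjustments (adjusted p = 8.05e-07; 0.199 with an estimated correlation). CDH5, the cadherin of endothelial junctions, rose from 1.13 ± 0.195 to 58 ± 9.1 CPM and the ETS factor FLI1 from 0.846 ± 0.204 to 23.8 ± 1.15 CPM. In the endoderm list 11 of 17 genes rose, by both adjustments, and SOX17, FOXA2, FOXA3 and CXCR4 were among those that fell. Its camera test did not pass (adjusted p = 0.0662, fry 0.00111; 0.0407 without day 4 replicate 1, 0.0376 with upper-quartile factors and 0.0256 with library size alone). SERPINA1, a secreted protease inhibitor, rose from 0.0741 ± 0.037 to 40.4 ± 4.12 CPM (542-fold), AFP, alpha-fetoprotein, from 0.138 ± 0.0534 to 51.2 ± 7.72 CPM, and TTR, transthyretin, from 3.17 ± 0.108 to 61.7 ± 12.5 CPM. In the epicardial and stromal list 10 of 15 genes rose, 12 adjusted over the list alone, and TCF21, ALDH1A2 and COL1A1 fell (adjusted p = 0.000724; 0.257 with an estimated correlation). COL3A1 rose from 214 ± 20.3 to 1730 ± 145 CPM.

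Of 20 pluripotency genes 12 fell from day 4 to day 6, and TDGF1, GDF3, LEFTY1 and LEFTY2 rose, by both adjustments (adjusted p = 0.000801; 0.24 with an estimated correlation). L1TD1, an RNA-binding protein gene of stem cells, fell from 68.9 ± 0.445 to 7.18 ± 0.444 CPM, and POU5F1, which shares reads with TCF19, from 41 ± 2.49 to 1.92 ± 0.635 CPM. Of 12 paraxial mesoderm genes 7 fell and none rose, by both adjustments (adjusted p = 0.00326; 0.207 with an estimated correlation). Of 13 epithelial genes 10 fell and KRT18 rose, by both adjustments (adjusted p = 0.000263; 0.226 with an estimated correlation), and CDH1, E-cadherin, fell from 56.6 ± 2.5 to 28.6 ± 2.02 CPM. KRT18 did not pass under every scaling tried. In the cell cycle list 26 of 27 genes fell, and all 27 adjusted over the list alone (adjusted p = 1.63e-14; 0.207 with an estimated correlation). MKI67, a marker of dividing cells, fell from 199 ± 9.98 to 87.1 ± 8.18 CPM. Primitive streak genes changed less evenly, with 7 of 16 lower and 4 higher (MIXL1, FGF8, EVX1 and CDX2), by both adjustments (down, adjusted p = 0.166, fry 0.000224). FGF8, a growth factor, rose from 1.73 ± 0.0547 to 26.5 ± 0.843 CPM and the T-box gene EOMES fell from 4.31 ± 1.34 to 0.58 ± 0.173 CPM. Of 12 cardiac mesoderm genes 6 fell and 5 rose (KDR, SNAI1, RSPO3, HAS2 and SMARCD3), by both adjustments (down, adjusted p = 0.544). Outside the lists, ABCB11, a bile salt transporter, fell from 15.8 ± 0.603 to 0.355 ± 0.132 CPM.

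Genes of DNA methylation and of Wnt and BMP signalling went both ways from day 4 to day 6. Of 14 DNA methylation genes 7 fell, by both adjustments, and TET2 and MBD1 were among those that rose (down, adjusted p = 0.191, fry 0.00624). UHRF1, which guides maintenance methylation, fell from 33.2 ± 1.08 to 18.4 ± 1.74 CPM. Of 12 Wnt targets 7 rose, and LEF1, NKD1, SP5 and LGR5 fell, by both adjustments (up, adjusted p = 0.333). LGR5, an R-spondin receptor, fell from 156 ± 0.954 to 4.61 ± 0.308 CPM, while DKK1 rose from 1.43 ± 0.232 to 18.7 ± 1.81 CPM. Of 10 BMP targets ID2, ID3, SMAD7 and BAMBI rose and MSX2 fell, by both adjustments; the median was 0.08, between −0.01 and 0.08 under other scalings (up, adjusted p = 0.279). Between 3 and 4 of the 10 rose over the scalings tried. BAMBI, a decoy receptor, rose from 241 ± 3.77 to 516 ± 33 CPM.

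The comparison of day 8 with day 6 asks how early cardiomyocytes differed from cardiac progenitors. Fewer genes changed than in either earlier step. Calcium handling, other cardiomyocyte and respiration genes rose further, while cell cycle, endothelial, epithelial and stromal genes fell. NPPA, atrial natriuretic peptide, rose from 15.2 ± 2.85 to 102 ± 13.3 CPM, with reads shared with NPPA-AS1. RIPPLY3, a repressor of T-box factors, fell from 10.2 ± 0.823 to 0.455 ± 0.0285 CPM (22.3-fold), and NPY, a neuropeptide, from 51.2 ± 4.09 to 6.69 ± 0.706 CPM. In all, 3810 rows were higher and 4703 lower, and among protein-coding rows 2841 were higher and 3358 lower. At a log2 fold change of at least 1, 526 were higher and 1237 lower, so that 29.8% of the calls were rises against 44.8% without the minimum. The 8513 changed rows became 5653 without day 6 replicate 1, 4800 without day 6 replicate 2 and 5385 without day 8 replicate 2.

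Of 14 other cardiomyocyte genes 10 rose from day 6 to day 8, 11 adjusted over the list alone, and none fell (adjusted p = 2.11e-06; 0.168 with an estimated correlation). CORIN, the protease that activates natriuretic peptides, rose from 71.4 ± 9.13 to 290 ± 4.81 CPM and VCAM1, a surface molecule of cardiomyocytes, from 77.8 ± 8.69 to 209 ± 5.83 CPM. Of 20 calcium handling genes 11 rose, 13 adjusted over the list alone, and CACNA1D and GJA1 fell (adjusted p = 0.000262; 0.168 with an estimated correlation). CACNA1G, a T-type calcium channel, rose from 11.3 ± 2.39 to 34.4 ± 1.84 CPM and GJA5, a connexin, from 5.17 ± 0.872 to 14.9 ± 0.902 CPM. Of 29 sarcomere genes 11 rose, 13 adjusted over the list alone, and ACTC1, MYOM2, ANKRD1 and SYNPO2L fell (adjusted p = 0.0411, fry 0.068; 0.393 with an estimated correlation, 0.101 without day 6 replicate 2, 0.106 without day 8 replicate 2 and 0.0722 without members that share reads). MYOZ2, a Z-disc protein gene, rose from 19.2 ± 1.37 to 58 ± 2.59 CPM, and ANKRD1, a stress-responsive ankyrin protein gene, fell from 148 ± 7.68 to 65.1 ± 2.35 CPM. Cardiac transcription factors went both ways, with 6 of 21 higher, 9 adjusted over the list alone, and 9 lower. Their median was −0.01, between −0.03 and 0.01 under other scalings (adjusted p = 0.583, fry 0.00681). IRX4 rose from 58.2 ± 9.46 to 145 ± 6.21 CPM and HOPX, a homeodomain protein gene, fell from 3.62 ± 0.31 to 1.83 ± 0.17 CPM.

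Of 21 oxidative phosphorylation genes 19 rose from day 6 to day 8, 20 adjusted over the list alone, and none fell, with a median of 0.37 (adjusted p = 2.07e-09; 0.248 with an estimated correlation). ATP5F1B, the β subunit of ATP synthase, rose from 855 ± 23.9 to 1140 ± 64.8 CPM. Of 27 cell cycle genes 19 fell, 20 adjusted over the list alone, and MCM3 rose, with a median of −1.02 (adjusted p = 4.86e-13; 0.237 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, fell from 143 ± 3.81 to 38.8 ± 3.93 CPM and CDC20, an activator of mitotic exit, from 29.4 ± 1.23 to 8.22 ± 0.0101 CPM. Of 17 endothelial and blood genes 13 fell, 14 adjusted over the list alone, and RUNX1 rose (adjusted p = 8.07e-06; 0.237 with an estimated correlation). VWF, von Willebrand factor, fell from 12.8 ± 1.83 to 1.68 ± 0.154 CPM and TAL1, a blood and endothelial factor, from 9.16 ± 1.31 to 3.29 ± 0.0249 CPM. Of 13 epithelial genes 12 fell and CLDN6 rose, by both adjustments (adjusted p = 4.91e-07; 0.174 with an estimated correlation), with the splicing factor gene ESRP1 going from 12.5 ± 0.984 to 4.95 ± 0.201 CPM. Of 15 epicardial and stromal genes 9 fell, 10 adjusted over the list alone, and ALDH1A2 rose (adjusted p = 0.00175; 0.269 with an estimated correlation). FN1, fibronectin, fell from 5040 ± 611 to 1790 ± 132 CPM. Of 12 cardiac mesoderm genes 8 fell and SMARCD3 rose, by both adjustments (adjusted p = 0.000397; 0.168 with an estimated correlation), and BMP4 went from 97.5 ± 13.3 to 30.8 ± 1.05 CPM. Of 10 BMP targets 7 fell and MSX2 rose, by both adjustments (adjusted p = 0.00121; 0.247 with an estimated correlation).

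Endoderm genes divided between day 6 and day 8. AFP, SERPINA1 and FGB rose, and 6 of 17 members fell, by both adjustments (down, adjusted p = 0.0618, fry 0.00191; 0.0228 without day 8 replicate 1 and 0.0482 with upper-quartile factors). HHEX, a homeobox gene of anterior endoderm, fell from 48.2 ± 1.15 to 9.05 ± 0.807 CPM and FOXA2 from 11.2 ± 0.473 to 2.23 ± 0.358 CPM. Of 20 pluripotency genes 8 fell, and TDGF1 and LEFTY2 rose, by both adjustments (adjusted p = 0.0103; 0.29 with an estimated correlation and 0.145 without day 8 replicate 1). LIN28A, which blocks let-7 maturation, fell from 311 ± 8.37 to 127 ± 5.51 CPM. Among 16 primitive streak genes MIXL1, FGF8, EVX1 and FOXH1 fell and none rose, and adjusted over the list alone WNT3 fell and EOMES and CDX1 rose as well (down, adjusted p = 0.0618, fry 0.00024; 0.0201 without day 8 replicate 1). MIXL1 did not pass without day 6 replicate 2 (adjusted p = 0.162). Of 12 paraxial mesoderm genes MEOX1 and PAX3 rose and DLL1 and FOXC1 fell, and adjusted over the list alone TBX6 fell as well (down, adjusted p = 0.151, fry 0.00976). MEOX1 and PAX3 did not pass without day 6 replicate 2 (adjusted p = 0.119 and 0.228). Glycolysis genes split, with GPI, ALDOC, TPI1 and GAPDH higher and PFKP, SLC2A1, SLC2A3 and PDK1 lower of 18, and adjusted over the list alone HK1 higher and HK2 lower (median 0.04, camera up with adjusted p = 0.68, fry down with adjusted p = 0.407). Of 14 DNA methylation genes DNMT3A and MBD3 rose and DNMT3B, UHRF1, TET1 and MBD1 fell (down, adjusted p = 0.216, fry 0.00388). UHRF1 did not pass without day 6 replicate 2 (adjusted p = 0.0723). Of 12 Wnt targets AXIN2, ZNRF3, DKK1 and APCDD1 rose and TCF7, NKD1, SP5 and LGR5 fell, and adjusted over the list alone NOTUM rose as well. Their median was 0.11 and their mean −0.11 (camera up, adjusted p = 0.583; fry down, adjusted p = 0.403).

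The comparison of day 8 with day 2 spans the whole course, from late mesoderm to early cardiomyocytes. Sarcomere and calcium handling genes ended far above their day 2 levels. Respiration genes ended less far above their day 2 levels, with a median log2 fold change of 1.05 against 7.82 for sarcomere genes. Cell cycle, pluripotency and primitive streak genes ended far below theirs. MYH6 rose from 5.85 ± 0.327 to 9220 ± 164 CPM (1580-fold), and TBX5 from 0.0977 ± 0.00768 to 153 ± 4.47 CPM (1560-fold). TBXT fell from 501 ± 9.43 to 0.221 ± 0.0984 CPM and WNT8A, a Wnt ligand of the streak, from 238 ± 0.0156 to 0.145 ± 0.0184 CPM. In all, 11516 rows were higher on day 8 and 11324 lower, and among protein-coding rows 6646 were higher and 6737 lower. Over all rows the larger side depended on the setting, with 10641 higher and 12194 lower with library size alone.

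All 29 sarcomere genes were higher on day 8 than on day 2 by both adjustments, with a median of 7.82 (adjusted p = 3.03e-17; 0.039 with an estimated correlation). MYH7, the β myosin heavy chain, rose from 0.362 ± 0.0979 to 534 ± 31.8 CPM and UNC45B from 0.25 ± 0.0378 to 352 ± 17.5 CPM. Of 21 cardiac transcription factors 19 rose and GATA6 fell, by both adjustments (adjusted p = 3.43e-10; 0.039 with an estimated correlation), and NKX2-5 reached 293 ± 26.2 CPM from 0.241 ± 0.145 CPM. Of 20 calcium handling genes 17 rose, and KCNJ2 and GJA1 fell, by both adjustments (adjusted p = 8.8e-07; 0.039 with an estimated correlation). JPH2, junctophilin 2, rose from 3.07 ± 0.0745 to 178 ± 4.93 CPM. Of 14 other cardiomyocyte genes 13 rose and none fell, by both adjustments (adjusted p = 2.41e-07; 0.039 with an estimated correlation), with MB, myoglobin, going from 0.152 ± 0.0522 to 45.5 ± 3.79 CPM. All 21 oxidative phosphorylation genes rose by both adjustments, with a median of 1.05 (adjusted p = 2.08e-08; 0.27 with an estimated correlation). Of 15 epicardial and stromal genes 13 rose, and ALDH1A2 and COL1A2 fell, by both adjustments (adjusted p = 9.51e-05; 0.23 with an estimated correlation), and LUM, lumican, rose from 0.071 ± 0.0518 to 61.7 ± 12.9 CPM. Of 17 endothelial and blood genes 14 rose, and VWF and RUNX1 fell, by both adjustments (adjusted p = 0.000699; 0.25 with an estimated correlation), and CDH5 went from 0.272 ± 0.0902 to 28.9 ± 3.02 CPM. Of 10 BMP targets 7 rose, and ID1 and MSX1 fell, by both adjustments (adjusted p = 0.0165; 0.285 with an estimated correlation).

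All 27 cell cycle genes were lower on day 8 than on day 2 by both adjustments, with a median of −3.02 (adjusted p = 2.47e-15; 0.196 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitosis, fell from 82.5 ± 0.693 to 6.66 ± 0.069 CPM. Of 20 pluripotency genes 17 fell, 18 adjusted over the list alone, and LEFTY2 rose (adjusted p = 2.06e-07; 0.143 with an estimated correlation). POU5F1 fell from 604 ± 19 to 1.49 ± 0.779 CPM, and PRDM14, a germline and stem cell regulator without a count on day 8, was at least 422-fold lower. Of 16 primitive streak genes 15 fell and FGF8 rose, by both adjustments, with a median of −7.56 (adjusted p = 5.48e-08; 0.039 with an estimated correlation). GSC, a homeobox gene of the organiser, had no count on day 8 and was at least 816-fold lower. Of 12 paraxial mesoderm genes 9 fell, and MEOX1, PAX3 and UNCX rose, by both adjustments (adjusted p = 0.00285; 0.196 with an estimated correlation), and DLL3, a Notch ligand, went from 795 ± 0.791 to 5.1 ± 0.291 CPM. Of 12 cardiac mesoderm genes 8 fell, and KDR, TMEM88 and SMARCD3 rose, by both adjustments (down, adjusted p = 0.0945, fry 1.16e-05). APLNR, the apelin receptor, fell from 2620 ± 43.2 to 60.6 ± 0.0373 CPM. Of 13 epithelial genes 11 fell, and KRT8 and KRT18 rose, by both adjustments (adjusted p = 0.000676; 0.23 with an estimated correlation). Of 12 Wnt targets 8 fell, and LEF1, RNF43, ZNRF3 and APCDD1 rose, by both adjustments (adjusted p = 0.0422; 0.196 with an estimated correlation and 0.0533 without day 8 replicate 2). The number that rose lay between 2 and 4 over the scalings tried. SP5, a direct Wnt target, fell from 116 ± 4.12 to 0.751 ± 0.115 CPM. Of 18 glycolysis genes 11 fell, and GPI, PFKM, PFKP and PDK1 rose, with 1 more adjusted over the list alone, SLC2A3 (down, adjusted p = 0.0926, fry 0.00244; 0.0402 without members that share reads). In the endoderm list 9 of 17 genes rose and 6 fell, or 10 and 7 adjusted over the list alone (up, adjusted p = 0.402, fry 0.0122), and AFP reached 196 ± 45.7 CPM from 0.0824 ± 0.0294 CPM on day 2. Of 14 DNA methylation genes 8 fell, by both adjustments, and DNMT3A, TET2 and MBD1 were among those that rose (adjusted p = 0.328, fry 7.14e-05). DNMT3B fell by 3.50 ± 0.04 on the log2 scale (adjusted p = 3.75e-09), and TET2, which oxidises methylcytosine, rose from 14.1 ± 0.836 to 50.4 ± 1.39 CPM.

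**Figure D3:**
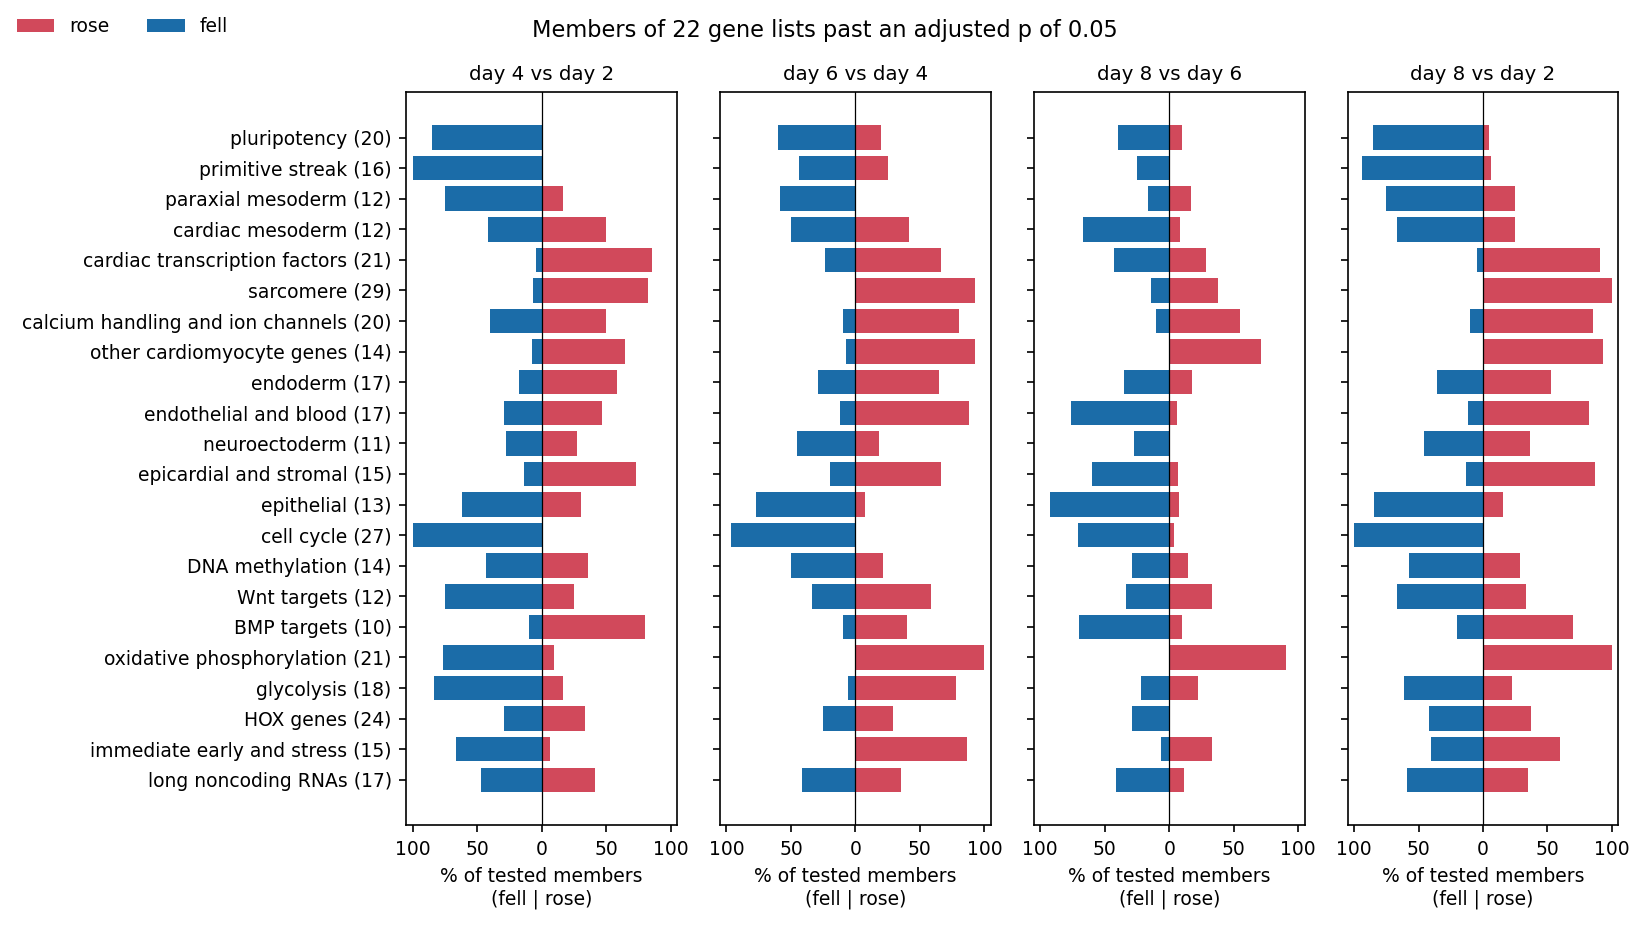
Percent of the tested members of each of 22 gene lists (number tested in brackets) that rose or fell past an adjusted p of 0.05, in each of 4 comparisons. Bars to the right count members that rose and bars to the left those that fell; all 27 cell cycle genes fell and all 29 sarcomere genes rose from day 2 to day 8.

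These tests rest on 2 libraries per day. A gene not called may still have changed. In the simulated comparison, with 200 of 37675 rows changed, the edgeR test found 62% of 2-fold changes. In the data 51% of rows were called from day 2 to day 4, so that share does not carry over to the real comparisons. Counts cover introns and both strands, so a value for a gene that shares reads can include transcripts of its neighbour.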

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

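Rows that overlap no other row, protein-coding rows alone, the table without mitochondrial and ribosomal DNA rows and the lists without shared members were tried after the data were seen; the other settings were set before the data were examined. With a minimum log2 fold change of 1 the changed genes were 8882 from day 2 to day 4, 5882 from day 4 to day 6, 1763 from day 6 to day 8 and 12358 from day 2 to day 8, since the minimum removes small changes; an adjusted p of 0.01 left 4623 from day 6 to day 8. The share of rises among the calls moved across 50% in each comparison but day 8 against day 6: from 48.7% to as much as 52.5% from day 2 to day 4 (fold minimum, or without day 2 replicate 2), from 51.2% to as little as 41.8% from day 4 to day 6 and from 50.4% to as little as 46.6% from day 2 to day 8 (both with library size alone). From day 6 to day 8 it ran from 29.8% (fold minimum) to 50% (upper-quartile factors). Rows that overlap no other row gave 5660, 4628, 2574 and 6668 in the same order and 7535 over the 4 days (2825, 1769, 1064 and 1877 highest on days 2, 4, 6 and 8), with 10779 rows tested. Protein-coding rows, 17400 tested, gave 12854 from day 2 to day 4, 11391 from day 4 to day 6 (5575 higher and 5816 lower), 13914 from day 2 to day 8 and 15855 over the 4 days (6034, 3470, 2260 and 4091 highest on days 2, 4, 6 and 8). Leaving out 1 library, with the remaining library of that day assumed to vary like the others, gave 4800 to 8248 changed genes from day 6 to day 8, 16684 to 19438 from day 2 to day 4, 12688 to 15819 from day 4 to day 6 and 20165 to 22241 from day 2 to day 8. TBXT from day 6 to day 8, not past the test, had a log2 fold change between −0.23 (without day 8 replicate 1) and 0.70 (without day 8 replicate 2); the cause was not tested. With the replicate number as a block there were 18862, 15052, 7421 and 21982 changed genes in the 4 comparisons, 7 of 380 named gene results were no longer past the test, and the list test of primitive streak from day 6 to day 8 passed (0.0474) while that of neuroectoderm did not (0.0668). Deviations from the day means correlated between −0.025 and 0.031 among libraries with the same number. Of the 380 named gene results, DESeq2 size factors left all 380 as they were, library size alone 378, DESeq2 378 and limma-voom 371; calls were ended for 46 by the fold minimum, for 23 by an adjusted p of 0.01, for 17 without day 6 replicate 2, for 12 each without day 6 replicate 1, day 8 replicate 1 and day 8 replicate 2, and for 6 to 10 without any other library. Other scalings put the median change of all rows between −0.09 and 0.02. They also moved the number of members called in some lists, such as 2 to 4 Wnt targets higher from day 2 to day 8. Of 88 list tests, camera run with an estimated correlation ended 49 calls, also for lists whose estimate lay below the preset 0.01. In the same tests fry ended 1 call and added 24. Depth limits what can be said of rows with few counts: 22739 rows were removed by the filter.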

Other observations

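The genes named here from the lists follow the rule set in advance, apart from members that make up a small count. HOX genes went both ways from day 2 to day 4. From day 2 to day 4, 8 of 24 HOX genes rose (HOXB1 to HOXB8) and 7 fell, HOXB13 among them, or 8 and 8 adjusted over the list alone (up, adjusted p = 0.842, fry 0.000176, with a median log2 fold change of −0.68). Reads are shared by 19 of the 24, among them HOXB2 to HOXB8, so the 8 rises may not be separate. HOXB1, a hindbrain and heart field patterning gene, went from 4.93 ± 0.852 to 15.6 ± 0.389 CPM and then to 0.607 ± 0.0843 CPM on day 6. From day 4 to day 6, 7 HOX genes rose and 6 fell, by both adjustments (camera up, adjusted p = 0.932; fry down, adjusted p = 0.709). From day 6 to day 8, 7 fell and none rose, by both adjustments (adjusted p = 0.00513; 0.248 with an estimated correlation and 0.781 without members that share reads). Over the whole course 9 rose and 10 fell, by both adjustments (median −0.55, mean −1.09, up, adjusted p = 0.955, fry 0.00113). Neuroectoderm genes changed unevenly. From day 2 to day 4, LHX2, POU3F2 and DLX5 rose of 11, by both adjustments, and OTX2 and NKX6-1 were among those that fell (median −0.73, up, adjusted p = 0.967). From day 4 to day 6, OTX2, ZIC1, SIX3, POU3F1 and POU3F2 fell, by both adjustments, and LHX2 was among those that rose (down, adjusted p = 0.355, fry 0.00386). From day 6 to day 8, OTX2, ZIC1 and LHX2 fell and none rose, by both adjustments (adjusted p = 0.0411; 0.248 with an estimated correlation, and between 0.0531 and 0.0845 without any 1 library other than day 6 replicate 1, 0.0516 with library size alone and 0.0758 without members that share reads). From day 2 to day 8, OTX2, ZIC1, SIX3, POU3F1 and NKX6-1 fell, by both adjustments, and LHX2, POU3F2 and DLX5 were among those that rose (median 0.20, mean −1.41, down, adjusted p = 0.758, fry 0.000153). Of these, NKX6-1 and DLX5 from day 2 to day 4 (adjusted p = 0.0888 and 0.0553), and NKX6-1 and SIX3 from day 2 to day 8 (0.181 and 0.112), did not pass without day 2 replicate 1. Nor did SIX3 from day 4 to day 6 without day 6 replicate 1 (0.0832) or LHX2 from day 6 to day 8 without day 8 replicate 2 (0.0874). OTX2, a forebrain and anterior patterning factor, fell from 102 ± 0.521 CPM on day 2 to 10.4 ± 0.438 CPM on day 8.

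Stress genes fell and then rose. Of 15 immediate early and stress genes 10 fell and EGR1 rose from day 2 to day 4, by both adjustments (adjusted p = 0.00252; 0.185 with an estimated correlation). From day 4 to day 6, 13 rose and none fell, with DDIT4 falling adjusted over the list alone (adjusted p = 0.00016; 0.161 with an estimated correlation). Over the scalings tried, 11 to 13 rose and 0 to 1 fell in this step. From day 6 to day 8, FOS, EGR1, HSPA1A, HSPA1B and HSPA5 rose and IER2 fell, by both adjustments (adjusted p = 0.0411; 0.269 with an estimated correlation, 0.142 without day 6 replicate 1, 0.0726 without day 8 replicate 2, 0.0568 and 0.0537 without day 4 replicate 1 and replicate 2). IER2 did not pass without day 6 replicate 1 (adjusted p = 0.115). The HSPA1A and HSPA1B rows held nearly equal counts, such as 19142 and 18890 in day 8 replicate 1. They may hold the same reads, so their rises may not be separate. From day 2 to day 8, 9 rose and 6 fell, by both adjustments (up, adjusted p = 0.471, fry 0.00544), with 7 to 9 higher over the scalings tried. CHAC1, a target of the integrated stress response, fell from 8.68 ± 1.56 CPM on day 2 to 0.824 ± 0.0548 CPM on day 4, and the chaperone gene HSPA5 stood at 693 ± 25.4, 284 ± 3.12, 413 ± 6.86 and 540 ± 13.7 CPM on days 2, 4, 6 and 8. Of 17 long noncoding RNAs 7 rose and 8 fell from day 2 to day 4, by both adjustments (up, adjusted p = 0.77, fry 3.81e-06). From day 4 to day 6, 6 rose and 7 fell, 9 adjusted over the list alone (down, adjusted p = 0.279, fry 0.000271). From day 6 to day 8, HAND2-AS1 and DANCR rose and 7 fell, 11 adjusted over the list alone (adjusted p = 0.00326; 0.168 with an estimated correlation). From day 2 to day 8, 6 rose and 10 fell, by both adjustments (camera down, adjusted p = 0.402; fry up, adjusted p = 4.56e-05). H19, an imprinted RNA, rose from 1.56 ± 0.134 CPM on day 2 to 330 ± 8.47 CPM on day 4 and stood at 911 ± 106 CPM on day 8. LINC-ROR, an RNA of pluripotent cells, fell from 4.67 ± 0.0891 CPM on day 4 to 0.105 ± 0.0247 CPM on day 6.

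The EMC10 row, of an endoplasmic reticulum membrane complex subunit, rose from 132 ± 0.136 CPM on day 4 to 5930 ± 1310 CPM on day 6 (log2 fold change 5.49 ± 0.15, adjusted p = 4.44e-07), and its tests were chosen after this was seen. If the whole gene had been transcribed more, the antisense row CTD-2545M3.2 across its middle exons should have risen with it on these unstranded counts, but its log2 fold change was 0.12. The nested row CTD-2545M3.8 rose from 8.91 ± 0.0592 to 1110 ± 252 CPM, and 0 of its 829 bases lie in a match of at least 95% identity and 50 bases elsewhere in the genome, so a near-identical copy in the reference does not account for the rise of that nested row; the rest of EMC10 was not searched. That row held 18.7 ± 0.135% of the EMC10 counts of day 6. Whether a transcript starts inside the row or inserted sequence was read there could not be told, since read positions were not analysed here.

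The yylncRNA rows moved with the gene in their names, over 370 pairs whose yylncRNA row overlaps no other row (median distance 502 bases): r between log2 fold changes was 0.83 from day 2 to day 4, 0.74 from day 4 to day 6, 0.41 from day 6 to day 8 and 0.84 from day 2 to day 8, across genes, which are not independent replicates. Each one-sided permutation p was 1e-04, the smallest that 10000 permutations can give. The permutations shuffled partners among the 370 pairs, so this p does not compare them with other close neighbours. The lowest r, 0.41 (95% bootstrap interval 0.28 to 0.54), stayed above the bound of 0.1 set in advance. Counts shared between overlapping rows alone therefore do not account for the correlation. Whether reads of the named gene fell in the yylncRNA row, beyond the end of that gene's own row, was not tested. Other close neighbours, 1335 pairs at most 635 bases apart, had r of 0.56, 0.48, 0.28 and 0.54 in the same order. These were not matched to the yylncRNA pairs for strand or expression, and only 1 row of a pair had to be free of overlaps. A difference from them can therefore reflect these features as well. The prediction set in advance asked for the same outcome in all 4 comparisons and was undecided; split afterwards, the difference was at least 0.26 (0.14 to 0.37) in the other 3 comparisons, and 0.13 (−0.02 to 0.29) from day 6 to day 8, where it could not be told from that of any neighbours.

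The rise of AFP, SERPINA1 and TTR from day 4 to day 6 may reflect a share of liver-like endoderm cells, and a second list of 18 liver secretory genes was set against it with a bound fixed before that list was tested. The bound was missed: 8 of the 18 rose and C3 fell, by both adjustments, where at least 9 were asked for (median 0.69; camera p = 0.0112, and 0.295 with an estimated correlation). By the bound set in advance the prediction failed. The exact 95% interval of that share, 21.5% to 69.2%, includes the bound but was added after the result was seen. It treats the 18 genes as independent of each other, so it does not undo that result. Of all rows tested, 8185 of 38745 were higher on day 6 than on day 4. APOH, APOC3, KNG1 and HP, none of them called, had means of at most 0.134 CPM on both days, where changes are hard to call. Missing the bound therefore does not show that liver-like cells were absent. From day 2 to day 8, 14 of the 18 rose and 2 fell. Reads from an adult liver sample would bring more ALB than AFP; ALB was 0.417% and 0.59% of AFP in the day 8 libraries, a test chosen after the values were seen.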
